A study of Rattus norvegicus with 2 samples.

How the data were processed

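Total RNA of AR42J cells was labelled with Cy3 and hybridised to one-colour NimbleGen arrays, 1 for untreated cells and 1 for cells given 200 µM TLC-S for 20 min, per the labels' protocols. The authors deposited 1 RMA intensity per target and array, and RMA is named, with no version, in the submitters' processing notes; its background correction and the scanner's settings were not given in the sources used here. The deposited intensities are on a linear scale, although the design fixed before the data were examined had assumed log2, and log2 was therefore taken here. The authors' up and down tables give the fold as a ratio and its log2, per the file headers. The authors' GO and pathway tables give a p-value for each term and the number of genes behind it, per the file headers, and were used as deposited. The deposited series values were equal to the sample files for all targets, and the authors' table of all targets differed from them by rounding. The 0 columns of array values left unmapped were counted by name.

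Of 26419 targets, 9740 were named through their RefSeq accession and 4955 through a gene ID in a gene table of assembly GRCr8, used for names alone, and 1644 kept the symbol of the authors' file; 10080 stayed unnamed. This gave 15575 genes. Unlisted targets were named less often (5492 targets) than listed ones (10847 targets). A gene with several targets was given the value of the target with the highest mean log2 signal. The log2 ratio is TLC-S over control. The number of arrays, 1 per group, limits the precision, so no test between groups was run; the intensity of random probes on each array is given with the results.

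The 24 gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 12 highest and 12 lowest log2 ratios among symbols other than LOC, RGD, MGC and chemoreceptor names, the 2 largest absolute ratios of each list, Actb and Gapdh, and the 6 highest and 6 lowest kinases, each with mean log2 signal at or above the median of all targets; and the 5 terms with the smallest p-value in each authors' table. Some genes that meet this rule are not reported here. Fos, the Egr genes and the genes named in the closing section outside this rule were chosen after their values were seen. Kinases are genes whose product name holds the word kinase without terms for inhibitors, anchors, binding, interacting or associated proteins, substrates or phosphatases; as only listed targets carry product names, their random lists were drawn from listed genes.

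A list's median was given its exact binomial (order statistic) 95% interval over genes and its percentile among 10000 random lists matched on 10 bins of mean signal, with a fixed random seed of 1. Genes of a list are not independent replicates, and both describe these 2 arrays. In data simulated for this comparison on 26419 targets, 200 genes at or above the median signal were set 1.5 log2 units higher or lower. A loess curve of log2 ratio on signal was then subtracted. Of the set genes, 91% of the higher and 88% of the lower passed 2-fold, as did 1.89% of the others at that signal. The simulated noise was set smaller than the observed spread of ratios, so these shares are not error rates of the real arrays. Of 100 simulated unshifted lists, 9% of lists of 15 genes and 3% of lists of 40 genes lay outside the central 95% (15575 genes). Those lists were drawn at random from genes with independent noise, so these shares check the ranking alone. They are no error rates for real lists, whose genes may vary together. Alternatives were the series values, the authors' table, median centring, loess (span 0.3, 3 robust iterations), signal limits, thresholds of 1.5-fold and 3-fold, an offset of 50, and the mean or dimmest target of a gene. Lists for leukocyte, lymphocyte, myeloid, epithelial and trypsin genes, for cholesterol and fatty acid synthesis, glycolysis, proteasome subunits, G2 and M phase, and G1 and S phase, the limit of 100 on both arrays and the kinase definition by record title were added after the data were seen. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.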

Results

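AR42J is a rat cell line derived from a tumour of the exocrine pancreas, and taurolithocholic acid 3-sulfate (TLC-S) is a sulfated bile acid used to model bile-induced injury of acinar cells. RNA of untreated AR42J cells and of cells exposed to 200 µM TLC-S for 20 min was each hybridised to 1 one-colour array that carried 26419 targets, nearly all of them read by 5 probes. There was 1 array in each group and thus no replicate check: each ratio compares these 2 arrays, no p-value was computed, and differences are given as higher or lower in TLC-S. Random-sequence probes gave an intensity of 44.7 in the control and 40.5 in TLC-S, and the median target gave 94.5 and 91.3, so that many targets lay close to background. Intensities reached 100 or more on both arrays for 11292 targets, the same 11292 that the authors listed. A gene with 1 array under 100 is given as a bound, at least N-fold, computed against an intensity of 100. Counts of targets or genes past 2-fold use the measured ratio instead.

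The first comparison asked which transcripts differed between TLC-S and control. Genes were ranked by measured ratio, a rank that the bounds of genes under 100 do not support by themselves. Among the highest genes in TLC-S were the growth factor Igf1, 16.8-fold higher, with all 3 of its targets higher, and Nsg2, a neuronal vesicle protein, at least 10.9-fold higher (44.0 in control, near the random probes, and 1094 in TLC-S). Txnip, which binds and inhibits thioredoxin, was 12.9-fold higher. The chemokine Cxcl10 was 8.10-fold higher and its receptor Cxcr3 at least 6.21-fold higher. Kif2c, a kinesin of the mitotic spindle, was 8.55-fold higher, Reln 8.53-fold, Mras 8.30-fold, Ets1 at least 5.75-fold and the cyclin-dependent kinase inhibitor Cdkn2c at least 4.43-fold.

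At the other end lay the trypsinogens, the precursors of the digestive protease trypsin. The intensity of Prss1 was 5337 in control and 603 in TLC-S (8.85-fold lower), that of Prss2 7536 and 856 (8.81-fold lower), and that of Prss3 15742 and 2183 (7.21-fold lower). The other genes among the 12 lowest were Mettl21cl1 (14.2-fold lower), Pimreg (10.1-fold), Smim5 (9.88-fold), the kallikrein Klk1c9 (at least 8.81-fold), Apoc4 (7.86-fold), Tbc1d30 (7.77-fold), Hopx (7.49-fold) and Gng8, whose measured intensity of 32.7 in TLC-S was under that of random probes and leaves only a bound of at least 2.84-fold. The largest difference among targets at 100 or more on both arrays was that of LOC684009, a predicted gene outside the naming rule and singled out after its values were seen, at 5759 in control and 114 in TLC-S (50.6-fold lower). Dym was 11.4-fold lower at its brighter target, but its 2 targets differed in sign, with log2 ratios of -3.51 and 0.92. That brighter target and those of Mettl21cl1, Pimreg, Smim5, Apoc4, Tbc1d30 and Prss3 come from predicted RefSeq records. The highest genes named above were all read by targets of curated records, so the lower values of these genes are less sure to report the named gene.

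Over all targets, 2084 were at least 2-fold higher and 1797 at least 2-fold lower in TLC-S, so that 53.7% of the 2-fold targets were higher (exact binomial 95% interval 52.1 to 55.3 over targets, which are not replicates). Among the 11292 targets at 100 or more on both arrays, 1124 were higher and 498 lower (69.3% higher), and 513 higher and 784 lower (39.6% higher) once a loess curve of log2 ratio on signal, which by construction centres the ratios at each signal, was subtracted. The balance of higher and lower targets thus depended on the scaling. The median log2 ratio was 0.06 over all targets and 0.24 over the 13210 targets at or above the median signal, where the SD was 0.80 and the central 95% of ratios ran from -1.69 to 1.66. As a gauge of noise near background, 1237 olfactory and vomeronasal receptor targets had an SD of 0.60, and 8.57% of them passed 2-fold. Of these targets, 44 were at 100 or more on both arrays, and the median was 44.9 in control and 42.9 in TLC-S. With all targets in 10 bins of mean signal, the SD was 0.44 in the dimmest bin and 0.58 in the brightest. It was 0.93 at signals of 91.7 to 151 and 0.94 at 151 to 309, where Nsg2, Ets1, Cxcr3 and Cdkn2c lay. These SDs include any true differences, but the receptor SD may understate the noise at such signals. Among 580 genes with 2 or more targets at 100 or more, the SD between targets of a gene was 0.42, against 0.65 over all those targets; such targets may share probes.

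**Figure D1:**
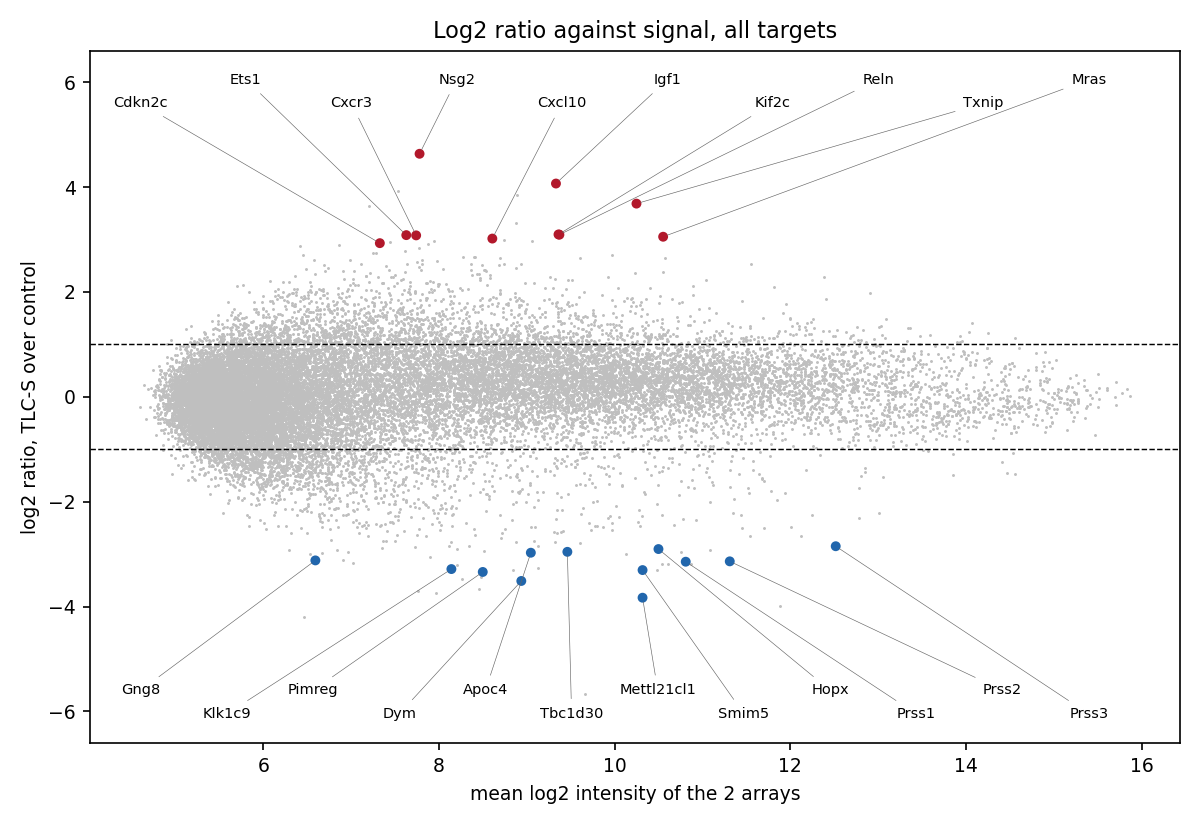
Each grey point is 1 of 26419 targets, with the mean log2 intensity of both arrays on the horizontal axis and the log2 ratio of TLC-S over control on the vertical axis; dashed lines mark 2-fold. Red and blue points are 10 of the genes with the highest and the 12 with the lowest ratio under the naming rule, by measured ratio; of those at 100 or more on both arrays, Igf1 is highest at 4.07 and Mettl21cl1 lowest at -3.83.

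The second comparison asked whether groups of genes stood apart, using 24 lists. Each list's median log2 ratio was placed among those of 10000 random lists of equal size and matched signal, as a description of these 2 arrays. Cell cycle genes were higher as a group: the median of 42 genes was 1.18 (95% interval 0.60 to 1.42), above every matched random list, whose median was 0.25. Of the 40 members at or above the median signal, 23 were at least 2-fold higher and 0 at least 2-fold lower. Ccnb2, a mitotic cyclin, was at least 5.80-fold higher, beside Cdkn2c. Immediate early and early stress-response genes had a median of 0.61 (0.25 to 0.86; 99.99th percentile). Of their 26 members at or above the median signal, 9 were at least 2-fold higher and 1 at least 2-fold lower by measured ratio, not by bound. The transcription factor Jun was 6.24-fold higher and the stress-response gene Gadd45b 5.34-fold higher. In contrast, Fos, Egr1, Egr2, Egr3 and Egr4 were among the members under 100 on both arrays. Of the 38 genes of this list, 22 were at 100 or more on both.

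Ribosomal protein genes had a median of -0.23 (-0.37 to -0.11; 0.01th percentile), with 40 of 45 members below 0 but only Rps16, 3.63-fold lower, past 2-fold. The Rps16 target, from a predicted RefSeq record, gave 706 in control, against a list median of 24599 (21024 to 29663). It may therefore not report that gene. Rps27 was 1.96-fold lower. Unfolded protein response genes and chaperones of the endoplasmic reticulum had a median of -0.16 (-0.39 to 0.06; 0.27th percentile). Derl3, of the degradation machinery, was 2.81-fold lower and the stress-induced factor Ddit3 2.79-fold lower, 2 of the 3 members past 2-fold. Genes commonly used as references were higher, with a median of 0.51 (0.13 to 0.72; 99.67th percentile): Ldha was 2.54-fold, Tubb5 2.24-fold, Actb 1.65-fold and Gapdh 1.57-fold higher. These 5 lists kept their sign and their place outside the central 95% of random lists in all 8 alternative settings. Of these settings, the series values and median centring cannot move a percentile. For the ribosomal, unfolded protein response and reference lists, the authors' table, the signal limit and the choice of target repeated the main median. With all kinase genes, 25 medians were placed in this way, of which about 1.25 would lie outside that range if the lists held unrelated genes. Genes of a list may vary together, so the 5 lists outside it do not measure a departure from chance.

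The other 19 lists lay within the central 95%. For acinar secretory proteins the median was -0.22 (5.86th percentile) over 31 genes, and only Prss1, Prss2 and Prss3 were at 100 or more on both arrays; restricted to the 7 members at or above the median signal, which include 4 trypsins, it was -2.56 and below every random list. Acinar transcription factors had a median of 0.40 (93.8th percentile), with Hes1 4.51-fold and Gata4 at least 2.05-fold higher. For NF-kB and inflammatory genes it was 0.22 (76.3rd percentile), and these went both ways, with Cxcl10 higher and the chemokine Cxcl1 at least 3.41-fold lower. Oxidative stress genes had 0.31 (82.4th percentile), with Txnip higher and Srxn1 at least 2.27-fold lower. Calcium stores, channels and pumps had 0.40 (97.0th percentile) and passed above the central 95% in 4 of 8 alternative settings; the calcium release channel Itpr3 was 4.20-fold and Itpr1 at least 1.45-fold higher. Bile acid and secretagogue receptors and transporters had 0.19 (94.9th percentile), with the cholecystokinin receptor Cckar at least 1.55-fold and Nr1i3 2.21-fold lower. By measured ratio, 2 of its 7 members at or above the median signal were at least 2-fold higher and 2 at least 2-fold lower. The lower ones include Cckar, whose bound does not reach 2-fold. Over these 7 members the median of 0.95 lay above the central 95% of random lists (99.2nd percentile). Apoptosis genes had 0.24 (66.8th percentile), with Faslg at least 2.68-fold lower and Birc5, which also acts in mitosis, 2.56-fold higher. Oxidative phosphorylation subunits had 0.37 (92.1st percentile), with Uqcrc1 2.30-fold and Uqcrfs1 1.98-fold higher.

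The median of exocytosis genes was 0.19 (59.7th percentile), with Cplx1 2.79-fold lower and Snap29 2.72-fold higher, and that of heat shock and cytosolic chaperones 0.10 (40.4th percentile), with Cct3 1.90-fold and Bag3 1.86-fold higher. Autophagy and lysosome genes had a median of 0.12 (15.1st percentile), with Atg12 at least 2.02-fold and Ctsc 2.27-fold higher; the signs of these 3 medians turned negative after loess subtraction. Endocrine markers had a median of 0.04 (78.5th percentile; -0.02 after median centring), with Pax6 1.74-fold higher and Ins2 at least 1.27-fold lower. Duct markers had -0.26 (10.9th percentile), with Cldn7 at least 1.79-fold and Cldn4 2.34-fold lower; over the 5 members at or above the median signal the median was -1.04, below the central 95% (0.55th percentile). Stellate cell and fibroblast markers had -0.14 (32.5th percentile), with Col5a1 1.52-fold lower and Tagln at least 1.26-fold higher. Leukocyte and endothelial markers had 0.07 (44.2nd percentile), with Mpo 4.35-fold and Cd4 at least 3.13-fold higher.

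**Figure D2:**
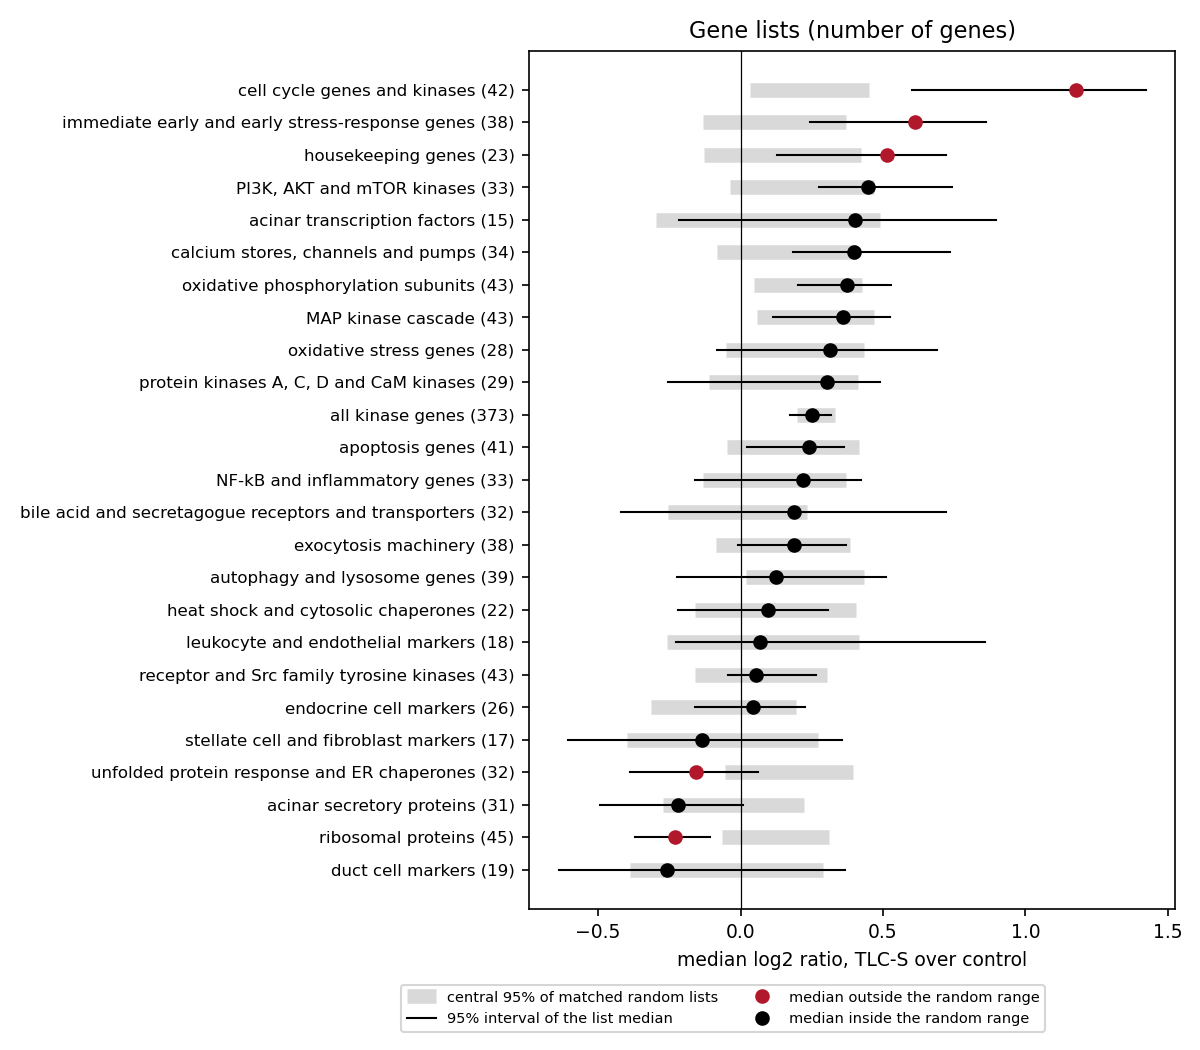
Points are the median log2 ratios of TLC-S over control of 24 gene lists and of all kinase genes, black lines their 95% intervals over genes and grey bars the central 95% of 10000 signal-matched random lists. The 5 red points lie outside the grey bars, from ribosomal proteins at -0.23 to cell cycle genes at 1.18.

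The third comparison concerned kinases, the gene class named by the series. The class was defined by product name, which the files give for targets at 100 or more on both arrays. Within it, the highest were Plk1 (5.80-fold higher), Aurka (4.86-fold) and Aurkb (3.50-fold), which act in mitosis, together with Melk (4.22-fold), Dbf4, the activator of a replication kinase (4.03-fold), and Plk3 (3.81-fold). Among the lowest were LOC688207 (5.98-fold lower), Ptk7 (3.84-fold), Fn3k (3.76-fold), LOC688480 (2.72-fold) and RGD1563741 (2.57-fold). All of these lowest kinases were read by targets of predicted RefSeq records, as were Melk, Dbf4 and Plk3 among the highest. Kinase genes as a class did not stand apart from genes of like signal: the median of 373 genes was 0.25 (0.17 to 0.32; 33.9th percentile of random lists), and turned to -0.01 after loess subtraction. Of these kinases, 41 (10.99%) were at least 2-fold higher and 8 (2.14%) lower, against 10.0% and 4.37% of the 10174 genes at 100 or more on both arrays.

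The MAP kinase cascade had a median of 0.36 (80.4th percentile), with Map2k6 at least 5.53-fold and Rps6ka2 3.36-fold higher. PI3K, AKT and mTOR kinases had 0.45 (96.7th percentile), with Sgk1 at least 2.22-fold and Pik3cb 2.62-fold higher. Protein kinases A, C, D and CaM kinases had 0.30 (85.0th percentile), with Prkar2a 3.04-fold higher. Camk1d was 2.96-fold higher at the brightest of its 3 targets, a log2 ratio of 1.57, but its dimmest target gave 0.23 and the mean over targets 0.63. Receptor and Src family tyrosine kinases had 0.05 (42.5th percentile) and a negative median after loess subtraction, with Kit at least 4.44-fold and Lyn 3.27-fold higher.

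The authors' deposited tables were set beside these values. All 1124 folds of the authors' deposited up table and all 498 of the down table matched the recomputed ratio within 1%, and the tables held exactly the targets at 100 or more on both arrays and past 2-fold. In the authors' deposited pathway table the smallest p-values of Fisher's exact test belonged to Cell cycle (36 of 125 genes, 4.42e-17), Oocyte meiosis (22 of 115), Progesterone-mediated oocyte maturation (18 of 86), Glycolysis / Gluconeogenesis (14 of 80) and Fructose and mannose metabolism (9 of 37). In the authors' deposited table of biological processes they belonged to cell cycle (103 of 646 genes), cellular process, M phase, cell cycle process and mitotic cell cycle. The authors' deposited table of cellular components led with intracellular, intracellular part, membrane-bounded organelle, intracellular membrane-bounded organelle and intracellular organelle, and that of molecular functions with binding, protein binding, nucleotide binding, catalytic activity and purine nucleotide binding. All but 1 of the genes in each GO table, and all 233 in the pathway table, were in the up table and 0 in the down table, so these terms describe higher genes. The GO tables' backgrounds, of 13542 to 15205 genes, were larger than the 10174 genes at 100 or more on both arrays.

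Cell type markers were also read for their level, with lists chosen after the data were seen. Of 27 acinar secretory genes other than trypsins, 0 were at 100 or more on both arrays, and their median intensity was 50.045 in control and 51.1 in TLC-S, whereas the 4 trypsin-family genes had medians of 6437 and 729. Of 35 pan-leukocyte genes, 34 reached 100 on both arrays, with medians of 927 and 1177. The same held for 20 of 24 B lymphocyte and plasma cell genes, 4 of 24 T and NK lymphocyte genes, 11 of 24 myeloid genes and 13 of 29 epithelial genes. Across the arrays, 10174 of 15575 named genes and 42.7% of all targets reached 100 on both.

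**Figure D3:**
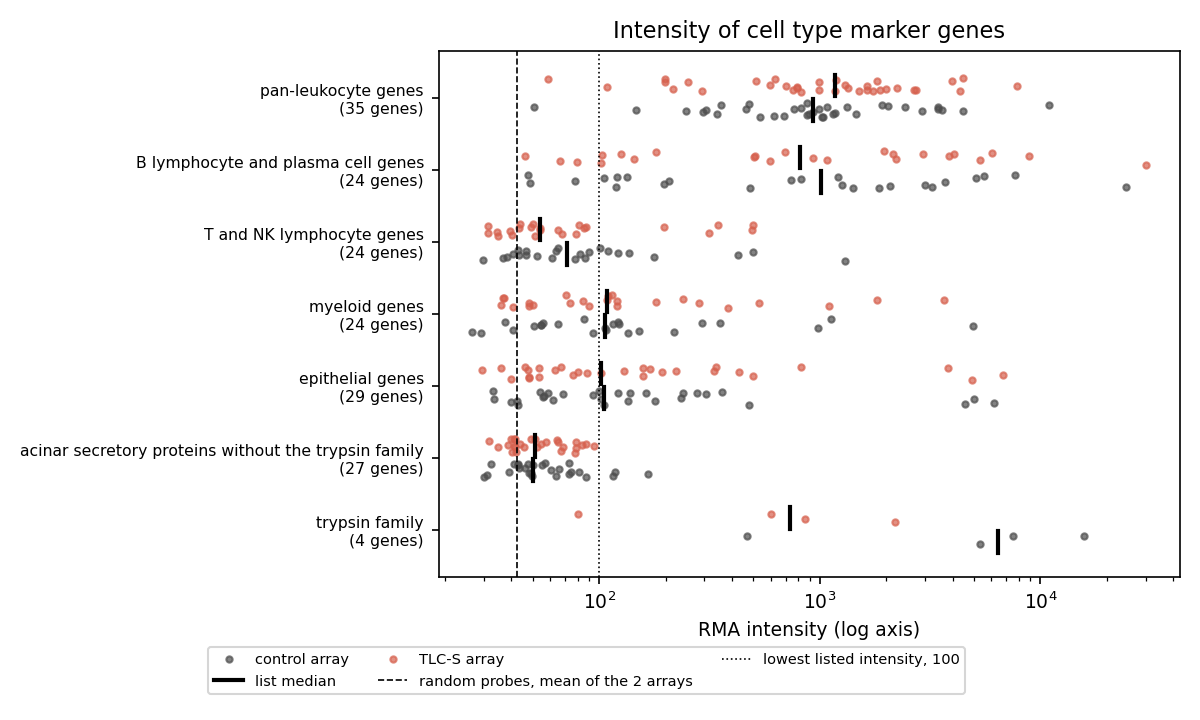
Each point is the RMA intensity (log axis) of 1 gene on the control array (grey) or the TLC-S array (red), with black bars for list medians, a dashed line for random probes and a dotted line at 100. Pan-leukocyte genes have a median of 927 in the control, and acinar secretory genes other than trypsins one of 50.045.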

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

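The limit of 100 on both arrays, its combination with loess and the kinase definition by record title were chosen after the data were seen. No paired analysis was possible because each group had 1 array, and leaving out a replicate and the planned use of raw intensities were not run, the latter because the values used here are normalized. The 5 lists outside the central 95% kept their side in all 8 alternatives. Of the lists inside it, 4 (acinar secretory, calcium, bile acid receptors and duct) left it in 1 or more. The series values and median centring cannot move a percentile. For ribosomal, unfolded protein response and reference genes, the authors' table, the limit at the median signal and the choice of target also repeated the main median. Of the alternative values of single genes and added lists, 7 moved by more than their spread and 1 reversed, but for single genes the series values, the authors' table to rounding and, where a gene has 1 target, the choice of target repeat the main value. Against 2084 higher and 1797 lower targets (53.7% higher), the authors' table and the limit of 100 on both arrays each gave 1124 and 498 (69.3%), by construction over fewer targets, and an offset of 50 gave 1093 and 701 (60.9%). Loess, which centres the ratios by construction, gave 513 and 784 (39.6%) with the limit of 100. Thresholds of 1.5-fold and 3-fold gave 5464 and 4379 (55.5%), and 483 and 535 (47.4%). A mean signal at or above the median left 912 lower (63.4% higher). The percent higher was 46.5 after median centring, 45.04 after loess, 56.0 with the 25th percentile as limit and 57.3 with the brighter array at or above the median. After loess the medians were 0.0684 for the MAP kinase cascade, 0.23 for PI3K, AKT and mTOR kinases, 0.00498 for apoptosis genes, -0.0124 for exocytosis genes, 0.13 for oxidative phosphorylation subunits and -0.00926 for all kinase genes. With members at or above the median signal they were -2.56 for acinar secretory proteins, 0.95 for bile acid and secretagogue receptors and transporters and -1.04 for duct markers, and the authors' table gave -3.14 for acinar secretory proteins. The dimmer target of Dym gave 0.92. The cause was not tested, apart from the smaller sets of genes or targets named. Signal over background is the limit for targets near or under the median signal of 91.7, with random probes at 44.7 and 40.5.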

Other observations

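All lists in this part were chosen after the data were seen, and the tests of each hypothesis were written after the values they measure had been seen. Genes of cholesterol and fatty acid synthesis were higher in TLC-S, with a median log2 ratio of 0.83 (95% interval 0.45 to 1.52) over 36 genes. Of the 34 members at or above the median signal, 15 were at least 2-fold higher and 0 at least 2-fold lower. Insig1, a sterol-regulated gene, had a log2 ratio of 2.38 and Fads2, a fatty acid desaturase, one of 2.67. Glycolysis genes had a median of 0.83 (0.30 to 1.13) over 27 genes, with Ldhb at 1.83 and Hk2 at 1.32, and several of them are also in the list of reference genes. Proteasome subunits had a median of 0.62 (0.45 to 0.85), with 39 of 39 genes above 0. These medians were 0.57, 0.78 and 0.37 after loess subtraction, and each lay above the central 95% of matched random lists in all 8 alternatives. Of these, the series values and median centring cannot move a percentile, and the mean over targets repeated each median. The 4 trypsin-family genes had a median of -2.99, and Try10, the dimmest of them, had an intensity of 470 in control and 80.0 in TLC-S.

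Of the pan-leukocyte genes, 34 of 35 reached 100 on both arrays, against 3 of 4 trypsin-family genes, 0 of 27 other acinar genes, 8 of 18 genes of the leukocyte and endothelial list, 4 of 24 T and NK genes and 11 of 24 myeloid genes. A few leukocytes among acinar cells would leave acinar genes bright. The trypsin family was bright, with a median of 6437 in control. The median over acinar secretory genes was 56.9 (47.4 to 74.7) with that family and 50.045 (43.2 to 73.0) without it. These low medians bear on that explanation only as far as these cells express those genes and their probes report. The test was also written after these values were seen, so it cannot decide. RNA largely from cells of the B lymphocyte or plasma cell lineage is a candidate explanation. Of 24 such genes, 83.3% (exact binomial interval 62.6 to 95.3 over the chosen genes) reached 100 on both arrays. The share was 16.7% (4.74 to 37.4) for T and NK genes and 44.8% (26.4 to 64.3) for epithelial genes. For comparison, 10174 of all 15575 named genes reached 100 on both arrays, so reaching 100 is not by itself particular to a marker list. The test as written asked for a larger percent. Its lists and wording were set after these values were seen, so it cannot decide. The explanation is left open here. A stricter condition, intervals that do not overlap, was not met by the epithelial genes. The bright trypsinogens (Prss1 at 5337, Prss2 at 7536 and Prss3 at 15742 in control), products of acinar cells, go the other way. Intensities in control were 24301 for Jchain, 7644 for Xbp1 and 5570 for Mzb1, which do not rank transcripts, as they come from different probes, and Xbp1, Derl3, Fkbp11 and Sdc1 are also known from secretory or epithelial cells.

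Cell cycle genes were higher in TLC-S. If a signal-dependent trend between the arrays explained this, loess subtraction would bring their median near 0. The median was 0.90 (0.40 to 1.13) after subtraction. That outcome could be foreseen, as the median was 1.18 before it, against 0.25 for signal-matched random lists. The largest median log2 ratio of any bin of mean signal was 0.33, which falls short of 1.18. The subtraction is thus no separate evidence beside the comparison with matched lists. A shift toward mitosis alone would leave G1 and S phase genes near 0. Their median after subtraction was 0.69 (0.40 to 0.87) over 48 genes, beside 1.51 (1.38 to 1.84) for 40 G2 and M phase genes. The G1 and S phase median was already 0.97 before subtraction. This test was written after that value was seen, so it describes these genes and cannot decide. A difference between the 2 cultures other than the compound cannot be told apart from the treatment, with 1 array per group. If synthesis had stopped fully at the start of the 20 min, the 12 lowest named genes would need half-lives of at most 5.22 to 13.3 min (median 6.37), with genes under 100 taken at their bound, and no value here gives their decay.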
